A study of Drosophila melanogaster with 12 samples.

How the data were processed

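The series holds 12 Affymetrix arrays of total RNA from Drosophila melanogaster fly heads, extracted with Trizol and labelled with biotin per the labels. The arrays are of 2 designs and come in 2 value tables, 1 with 8 arrays and 1 with 4 arrays. The values in both tables are intensity values on a linear scale that the authors deposited, and GCRMA is the method named in the submitters' processing notes, with no version given. The settings of GCRMA, the probe set definitions used and whether the 2 tables were normalized apart are not given in the sources used here. No test was made across the tables.

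The log base of the deposited values had to be settled from the values. The highest deposited intensity was 5374153 in the 8-array table and 3300359 in the 4-array table, above the 65535 that a 16-bit scanner can give. The natural logs of the values ran from 1.84 to 15.5 and from 0.97 to 15.01, which is the range of GCRMA values on the log2 scale, whereas log2 of the deposited values reached 22.36. The bacterial spike-in controls cre and bioB differed by 5.41 and 5.05 in natural logs. The natural log of each deposited value was therefore read as the log2 expression level, on the reading that values were exponentiated with base e before deposit. The plan had been to take log2 of a linear table, so this scale was chosen after the values were seen. With log2 of the deposited values, every change and its error would be 1.44 times as large, and the test statistics, p-values and counts would be the same. All log2 changes and folds below rest on this reading.

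The labels gave treatment for all arrays, and a Zeitgeber time of 4 or 16 h for 7 arrays of the 8-array table. One vehicle array of the 8-array table has no time in its label. It was left out of every main test and entered only an alternative over all 8 arrays. In the 4-array table no array has a labelled time. One of its vehicle arrays has no replicate number in its label and is called replicate 3 here, as a name only. No 2 arrays of a table held identical values. Nothing in the labels says that replicates came from separate groups of flies, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

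Control probe sets were left out, 183 in the 8-array table and 44 in the 4-array table, which left 18769 and 13966 probe sets. Kept for testing were probe sets whose mean over the arrays of the table lay above the 40th percentile, 11261 and 8379 of them. Probe sets were named from the platform annotation, with symbols updated through gene identifiers from a RefSeq gene table of assembly Release 6 plus ISO1 MT. Of the probe sets on the 8-array design, 13647 had 1 gene, 402 had several and 4720 had none, and 13544 of the names were found in that gene table. On the 4-array design these numbers were 12443, 327 and 1196, with 12394 names found. No gene was named from a probe set with several genes. A gene with several probe sets is represented by the one with the highest mean level. No coordinates are given because no genome build is named with the data.

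Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend; statmod 1.5.0), with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. The DEX effect on the arrays with a labelled time was the treatment coefficient of an additive fit of time and treatment over 3 vehicle and 4 DEX arrays, and the time effect was the other coefficient of that fit. The DEX effects at ZT4 and ZT16 and their difference came from a fit with 1 mean per treatment and time, in which the single ZT4 vehicle array is assumed to vary like the others. The DEX effect on the 4-array table compared 2 DEX with 2 vehicle arrays. The effects on the 2 designs were set beside each other by correlation across genes, which are not independent replicates.

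The main designs, the alternatives, the 21 gene lists and the rule for named genes were fixed before the data were examined, except where an addition is said to be later. Lists with at least 5 kept genes were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Single genes were also adjusted over the members of their list alone. That adjustment does not cover the number of lists and comparisons, so some calls over a list alone can be false. For fry, the directional test is meant throughout, not its mixed test for changes in either direction. Named genes for each DEX comparison are the 10 largest rises and falls past the threshold, filled by smallest p to 5 per direction where fewer pass. For the time effect and for the difference between times the rule takes 5 in each direction. Every core clock gene is named in every comparison, and the 4 members with the smallest p from each list that passes.

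The fits were tested on simulated data with 200 changed probe sets among the 11261 of the timed fit. A log2 change of 1 was recovered in 72.6% and a change of 2 in 97.8% of cases, with 5.2% false calls. For the 8379 probe sets of the 4-array fit the recovery was 86.4% and 99.4%, with 7.9% false calls. For the difference between times the recovery was 19.6% and 59% at these sizes. The simulated noise was normal, independent between probe sets and of the same spread on every array, so these rates need not hold for the real arrays. In the real timed fit, tim with a change of 3.21 had an adjusted p of 0.304 in limma. A simulated list of 8 genes shifted by 1 was found by camera in 50 of 50 draws, and an unshifted one in 1 of 50. These draws used the preset correlation, an unadjusted p under 0.05 and genes that varied independently. They do not test lists whose members vary together, and the estimated correlation of the core clock list was 0.71 for DEX on the arrays with a labelled time. Alternatives covered the filter, the moderation, quantile normalization, median centring, array weights, the threshold, replicate blocks and each array left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.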

Results

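Gene expression was measured in heads of flies that carry CLKGR, known in this field as a fusion of the clock transcription factor CLOCK (CLK) with the hormone-binding part of the glucocorticoid receptor. Dexamethasone (DEX) is a glucocorticoid that activates such a fusion. Cycloheximide (CHX) blocks protein synthesis and was present in both arms, so that the arms differ in DEX against its vehicle. The question named by the series is which genes are targets of CLK. Of the 12 arrays, 7 have a labelled Zeitgeber time (ZT, hours since lights on): 1 vehicle and 2 DEX arrays at ZT4, and 2 vehicle and 2 DEX arrays at ZT16. They belong to a table of 8 arrays, whose remaining array is a vehicle array without a labelled time. A second array design holds 4 arrays without a labelled time, 2 vehicle and 2 DEX. Median levels of the kept probe sets lay between 3.45 and 3.51 on the log2 scale in the 8-array table and between 3.43 and 3.51 in the 4-array table. The ZT16 vehicle replicate 1 had the lowest mean correlation with the other arrays of its table, 0.945, against 0.952 to 0.969 for the others. It is called the array that stood apart below, though the gap to the next array is small.

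The first comparison asks which transcripts differ between DEX and vehicle on the arrays with a labelled time. Among the genes with the smallest p-values were the clock genes tim and per. The clock repressor gene timeless (tim) had a mean level of 9.63 ± 1.07 (SD, n = 4) with DEX and 6.21 ± 0.64 (SD, n = 3) with vehicle, a log2 change of 3.21 ± 0.40 (SE) adjusted for time, or 9.25-fold. Its partner period (per) differed by 2.63 ± 0.35 (SE), or 6.20-fold, and the transcription factor gene vrille (vri) by 1.61 ± 0.30 (SE), or 3.06-fold. In all 4 DEX arrays the levels of tim, per and vri lay above those of all 3 vehicle arrays. No probe set passed limma's test after Benjamini-Hochberg adjustment over all 11261, with a smallest adjusted p of 0.202. At an unadjusted p under 0.05 there were 382 probe sets, 184 higher and 198 lower with DEX, where chance gives 563. That count was 250 without DEX ZT4 replicate 1 and 596 without vehicle ZT16 replicate 2, and with array weights it was 955, above the number chance gives.

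Of the 8 core clock genes, 3 rose when adjusted over the list alone, and none over all probe sets. These were tim and per, each with a limma adjusted p of 0.000471 over the list, and vri with 0.00248. The remaining 5 did not pass. The repressor gene clockwork orange (cwo) had a log2 change of 1.40 ± 0.54 (SE), which passed over the list without DEX ZT16 replicate 2 (1.96) and with array weights, and was 0.83 without DEX ZT16 replicate 1. Pdp1, an activator of Clk, had 0.30 ± 0.33. Clk itself had -0.35 ± 0.23, its partner gene cycle (cyc) -0.33 ± 0.24 and the photoreceptor gene cryptochrome (cry) -0.06 ± 0.21. The other probe sets of tim and cwo gave 3.51 and 1.68. As a list the core clock genes passed camera upward, with a median of 0.85 and an adjusted p of 0.00115 in limma. That call was lost with an estimated correlation, at an adjusted p = 0.945.

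**Figure D1:**
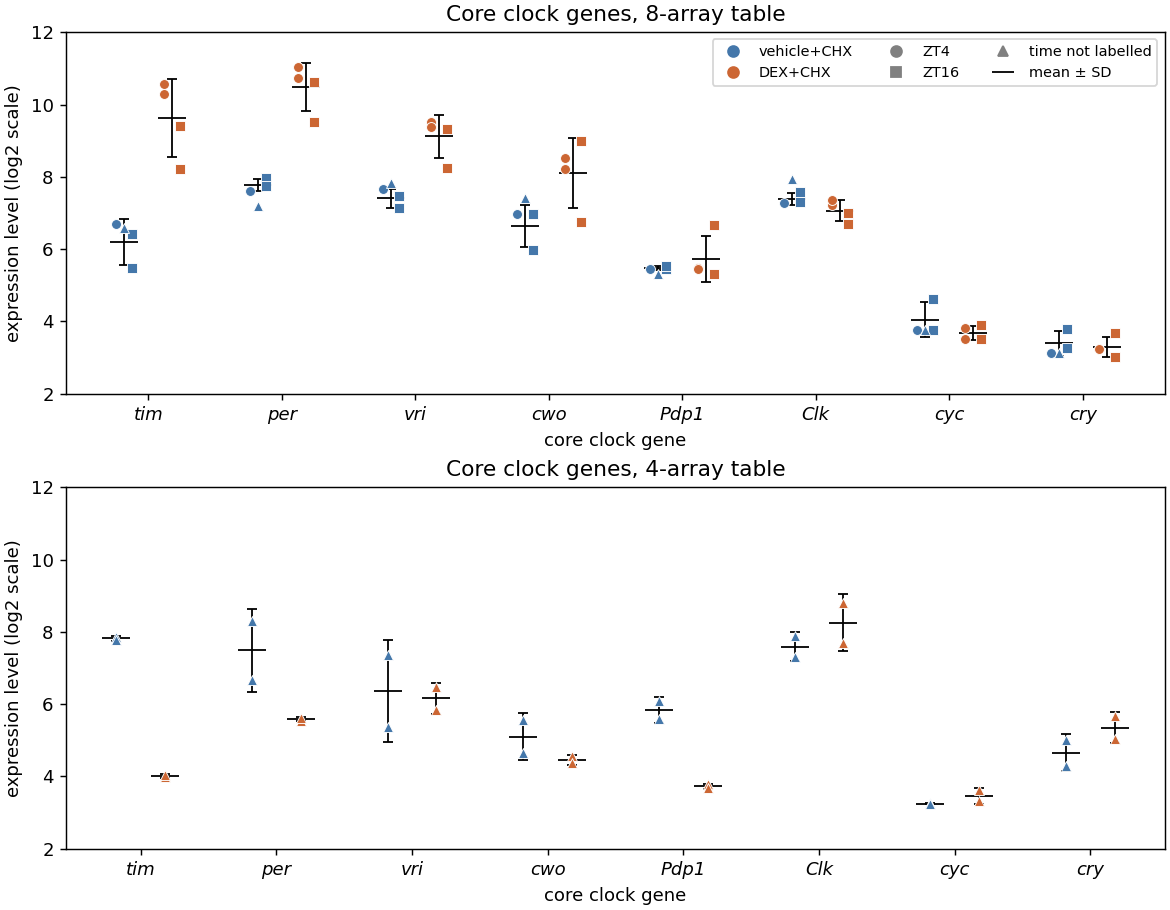
Expression levels (log2 scale) of the 8 core clock genes on each array, for the 8-array table (top) and the 4-array table (bottom). Points are arrays, coloured by treatment and shaped by labelled time; bars are the mean ± SD per treatment over the tested arrays, so the vehicle array without a labelled time in the top panel is drawn but not averaged. The level of tim was 9.63 with DEX against 6.21 with vehicle in the 8-array table and 4.02 against 7.82 in the 4-array table.

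Beyond the clock, MFS14, a member of the major facilitator superfamily of transporters, differed by 2.43 ± 0.27 (SE), or 5.39-fold. CG15096 differed by 2.44 ± 0.33 and CG9498 by 2.04 ± 0.33. The genes with the smallest p among those lower with DEX were CG15515 at -1.33 ± 0.27, CG14567 at -1.53 ± 0.32 and stw at -0.58 ± 0.12. Also among them were CG14642 at -0.42 ± 0.10 and the cohesin gene SMC3 at -0.24 ± 0.05. The DEX mean of SMC3 (2.71) lay below the 2.779 of the filter on dim probe sets, and that of stw (2.83) just above it. The sizes of both changes are therefore uncertain. None of these 8 genes passed over all probe sets, and nor did sug, named next (limma adjusted p 0.994). Adjusted over the list alone, MFS14 rose as 1 of 23 rhythmic output genes, with a limma adjusted p of 0.000825, and sugarbabe (sug), a sugar-responsive zinc finger gene, rose as 1 of 18 insulin and starvation genes by 2.13 ± 0.46, with 0.0402. The call for sug was lost without the ZT4 vehicle array (adjusted p 0.388 over the list), DEX ZT4 replicate 1 (0.123) or 2 (0.129), or vehicle ZT16 replicate 1 (0.143) or 2 (0.0962), while that of MFS14 held without any single array. In limma's test 18 probe sets, all higher with DEX, passed when DEX ZT16 replicate 2 was left out. The adjusted p of MFS14 and per was then 0.0174, of tim 0.0193 and of vri 0.0406.

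The bHLH-Orange list, which holds the Enhancer of split genes that act downstream of Notch and the clock gene cwo, was the second of 21 lists to pass camera. Its 9 measured members had a median change of 0.49 and an adjusted p of 0.00115 in limma, against an adjusted p = 0.945 with an estimated correlation. No member passed when adjusted over the list alone. The members with the smallest p, apart from cwo, were E(spl)mbeta-HLH at 2.16 ± 0.62 (SE), E(spl)m2-BFM, a Bearded family gene of the same locus, at 2.05 ± 0.67 and E(spl)m3-HLH at 2.10 ± 0.81. The vehicle means of E(spl)m2-BFM (2.76) and E(spl)m3-HLH (2.74) lay below the 2.779 of the filter on dim probe sets, so the sizes of these changes are uncertain, and that of E(spl)m3-HLH was 1.28 without DEX ZT16 replicate 1. Without the single ZT4 vehicle array the list's adjusted p in camera was 0.0815. Marker lists of cell types in the head did not pass, with median changes of -0.04 for neurons, 0.05 for glia, -0.08 for fat body, -0.06 for muscle and -0.03 for haemocytes. Heat shock genes and the proteasome came closest among the rest, both with an adjusted p of 0.0651 in limma. The kinases and regulators of the clock had a median change of -0.06 and rhythmic output genes 0.07. The 19 lists that did not pass had adjusted p between 0.0651 and 0.87, and 4 of them had a median of the opposite sign to the camera direction, those of fat body, activity-regulated, insulin and starvation, and odorant binding genes.

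The 4-array table asks the same question of arrays without a labelled time. Here tim fell by 3.80 on the log2 scale on the arrays labelled DEX, from 7.82 ± 0.07 (SD, n = 2) to 4.02 ± 0.05 (SD, n = 2). This was the only probe set of 8379 past the threshold, with an adjusted p of 0.0246 in limma. The other probe sets of tim had changes of -2.11 and -0.14. At an unadjusted p under 0.05 there were 454 probe sets, 268 higher and 186 lower, where chance gives 419. That count was 1305 without vehicle replicate 2, 689 without DEX replicate 1 and 929 without DEX replicate 2. Adjusted over the list alone, 3 of 8 core clock genes fell in limma's test. They were tim, Pdp1 with a change of -2.10 ± 0.22 (SE) and an adjusted p of 0.000425 over the list, and per with -1.90 ± 0.53 and 0.0356, which did not pass with median centring (0.118), the stricter filter (0.0581) or no mean-variance trend (0.0687). The change of per was -1.09 without vehicle replicate 2 and -2.71 without vehicle replicate 3. The remaining 5 did not pass: vri had -0.21 ± 0.66, cwo -0.64 ± 0.32, Clk 0.67 ± 0.44, cry 0.69 ± 0.33 and cyc 0.21 ± 0.13. Over the arrays left out vri ran from -1.20 to 0.79, cwo from -1.10 to -0.19 and Clk from 0.11 to 1.22. The ranges were 0.33 to 1.05 for cry and 0.06 to 0.37 for cyc.

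Other genes with small p-values on the arrays labelled DEX of the 4-array table were CG15096 at -2.99 ± 0.29 (SE), CG8008 at -2.13 ± 0.21 and CG34112 at -1.37 ± 0.18. In the other direction they were CG16713 at 1.94 ± 0.23, the NF-kappaB family gene dorsal (dl) at 1.48 ± 0.12, Srp72, a subunit of the signal recognition particle, at 0.93 ± 0.11, yin at 0.88 ± 0.09 and CG4198 at 0.66 ± 0.09. None of these 8 passed, with limma adjusted p between 0.109 and 0.312. The DEX mean of CG34112 (2.87) and the vehicle mean of yin (2.82) lay below the filter level of 2.924 on this table. The sizes of both changes are therefore uncertain. The call for tim was lost with quantile normalization, at an adjusted p of 0.22 in limma, with median centring at 0.199, with array weights at 0.0504, and without vehicle replicate 3 (0.312) or 2 (0.239). Leaving out DEX replicate 1 gave 192 probe sets past the threshold and leaving out DEX replicate 2 gave 314, fits in which the lone DEX array is assumed to vary like the vehicle arrays. With no filter on dim probe sets there were 23, among them tim and the 8 genes just named.

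Among the lists on the 4-array table, heat shock and chaperone genes passed camera, higher on the arrays labelled DEX, with a median of 0.28 and an adjusted p of 0.0219 in limma. The adjusted p = 0.755 with an estimated correlation. None of its 11 members passed, and the smallest p-values belonged to Hsp68 at 0.49 ± 0.24 (SE), the co-chaperone gene starvin (stv) at 0.60 ± 0.32, Hsp27 at 0.45 ± 0.25 and Hsp26 at 0.35 ± 0.22. The list's adjusted p was 0.0879 over all probe sets of its genes, 0.191 with quantile normalization, 0.0818 with median centring, 0.27 without vehicle replicate 3 and 0.42 without DEX replicate 1, all but the first added after seeing the data. The core clock list had a median of -0.42 and an adjusted p of 0.185, and the 20 lists that did not pass ranged from 0.185 to 0.803. Adjusted over the list alone, the GABA transporter gene Gat fell as 1 of 14 glial genes, with a change of -0.54 ± 0.09. Its limma adjusted p was 0.0133 over the list and 0.397 over all probe sets. The medians of neuronal and odorant binding genes and the mean of female fat body genes had the opposite sign to their camera direction. The spike-in control bioB, added to each sample in equal amount by the usual protocol, read 10.04 and 9.98 on the vehicle arrays and 9.39 and 9.35 on the arrays labelled DEX. The control bioC read 10.76 and 10.78 against 10.18 and 10.17, and cre 14.81 and 14.80 against 14.76 and 14.58. On the 8-array table bioB ran from 9.09 to 10.56, and both of these were vehicle arrays.

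**Figure D2:**
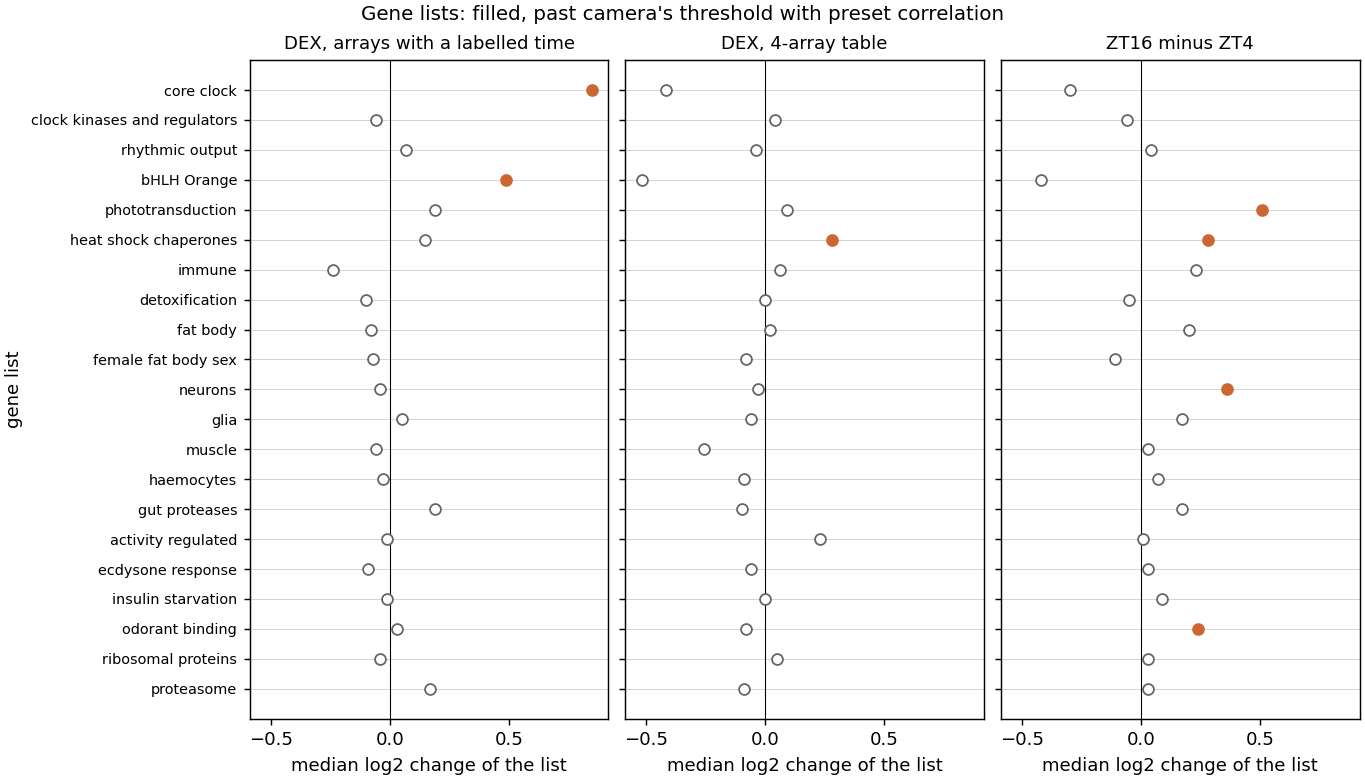
Median log2 change of each of the 21 gene lists in the DEX comparison on the arrays with a labelled time (left), the DEX comparison on the 4-array table (middle) and ZT16 minus ZT4 (right). Filled points passed camera with the preset correlation: 2, 1 and 4 lists; 0 passed in any panel with an estimated correlation.

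The 2 DEX comparisons share no array, so each can be set against the other. Over the 5514 genes kept in both, the log2 changes correlated across genes with a Pearson r of -0.34 and a Spearman rho of -0.10. Among the 20 genes with the smallest p on the arrays with a labelled time, 19 had the opposite sign on the 4-array table, and among 50 such genes 42 had it. Among the 20 genes with the smallest p on the 4-array table, 14 had the opposite sign on the arrays with a labelled time, and among 50 such genes 39 had it. Exact binomial tests across genes, which are not independent replicates, gave p = 4.01e-05 and p = 1.16e-06 for the first selection and p = 0.115 and p = 9.02e-05 for the second. Of the 50 chosen on the arrays with a labelled time, 14 had an unadjusted p under 0.05 on the 4-array table, and all 14 had the opposite sign. For tim, the gene called on the 4-array table, the changes were 3.21 and -3.80. MFS14 had 2.43 and -2.47, CG15096 2.44 and -2.99, per 2.63 and -1.90, and CG8008 2.22 and -2.13. Over all 5514 genes, 2795 had opposite signs and 2719 the same sign. The correlation was -0.15 without vehicle replicate 2 of the 4-array table.

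**Figure D3:**
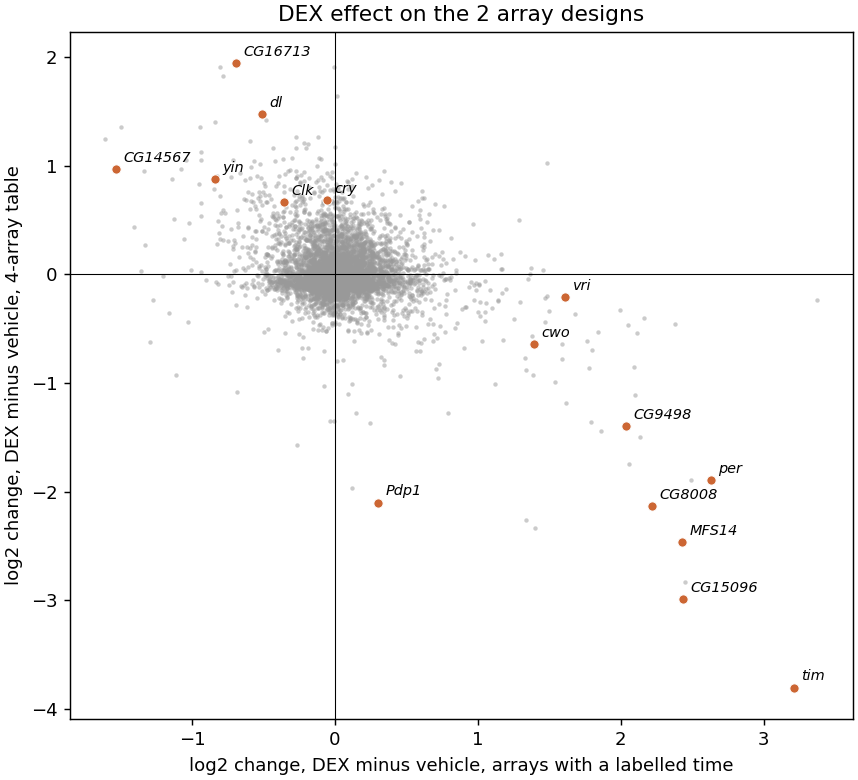
Log2 change (DEX minus vehicle) of each of 5514 genes on the arrays with a labelled time (horizontal axis) and on the 4-array table (vertical axis). Each point is a gene, and named genes are coloured; tim lies at 3.21 and -3.80, and Pdp1 at 0.30 and -2.10.

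The third comparison sets night (ZT16) against day (ZT4) over both treatments. Neuronal genes were higher as a group at ZT16, with 25 of 28 measured members positive, a median change of 0.36 and a camera adjusted p of 5.08e-08 in limma. Phototransduction genes were higher as a group too, with 16 of 19 positive, a median of 0.51 and an adjusted p of 6.12e-07. For both lists the adjusted p = 0.65 with an estimated correlation, while both passed with the preset correlation whichever single array was left out. One gene, the retinal pigment cell dehydrogenase gene Pdh, rose when adjusted over the list alone, by 2.60 ± 0.35 (SE), with a limma adjusted p of 0.00285 over the list and 0.563 over all probe sets. Further phototransduction genes with small p-values were inaD at 0.80 ± 0.29, inaC at 0.56 ± 0.21 and the arrestin gene Arr2 at 0.56 ± 0.18. Among neuronal genes these were Gad1, which makes GABA, at 1.07 ± 0.26, the potassium channel gene Sh at 0.96 ± 0.30, Snap25 at 0.69 ± 0.20 and ChAT, which makes acetylcholine, at 0.63 ± 0.17, and 0 of the 28 passed over the list alone. The level of the Act5C control was 6.05 on ZT16 vehicle replicate 1, the array that stood apart, and between 6.73 and 8.90 on the other arrays of the table.

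Heat shock genes and odorant binding proteins also passed camera at ZT16, with medians of 0.28 and 0.24 and adjusted p of 0.0203 and 0.0291 in limma. Both had an adjusted p = 0.877 with an estimated correlation, and no member of either passed over the list alone. The heat shock members with the smallest p were Hsp68 at 0.83 ± 0.25 (SE), Hsp27 at 0.74 ± 0.26, DnaJ-1 at 0.55 ± 0.27 and stv at 0.40 ± 0.20. Among odorant binding proteins they were Obp99d at 1.75 ± 0.45, Obp44a at 0.86 ± 0.39, Obp69a at 0.77 ± 0.37 and Obp19a at 0.43 ± 0.23. The heat shock call was lost without DEX ZT4 replicate 2 (adjusted p 0.26), vehicle ZT16 replicate 2 (0.0959) or DEX ZT16 replicate 2 (0.285). That of odorant binding proteins was lost without vehicle ZT4 replicate 2 (0.0802), DEX ZT4 replicate 2 (0.26), vehicle ZT16 replicate 2 (0.23) or DEX ZT16 replicate 1 (0.466).

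No single probe set passed for time in limma, with a smallest adjusted p of 0.418 and 402 probe sets at an unadjusted p under 0.05, where chance gives 563. The count was 252 without DEX ZT4 replicate 1 and 627 without DEX ZT16 replicate 2, and with array weights it was 676, above the number chance gives. The genes named by the smallest p were, apart from Pdh, the eye gene retinin at 3.21 ± 0.58 (SE), the neuropeptide-like gene Nplp3 at 1.27 ± 0.22, Tsp5D at 0.64 ± 0.12 and Rtc1 at 0.36 ± 0.07. With lower values at ZT16 they were the cytochrome P450 gene Cyp6d5 at -1.85 ± 0.23, the stress-induced gene TotC at -2.05 ± 0.40, Zcchc7 at -0.74 ± 0.14, the histone acetyltransferase gene mof at -0.60 ± 0.11 and CG8607 at -0.55 ± 0.11. Both means of Rtc1, 2.84 with DEX and 2.82 with vehicle, lay just above the 2.779 of the filter on dim probe sets. So did the DEX mean of CG8607 (2.79). The sizes of the changes of Rtc1 and CG8607 are therefore uncertain. Adjusted over the list alone, Cyp6d5 fell as 1 of 42 detoxification genes (limma adjusted p 0.00312). TotC did so as 1 of 17 immune genes (0.0237). Among 18 insulin and starvation genes, the adipokinetic hormone receptor gene AkhR rose by 0.61 ± 0.14 and the lipid droplet gene Lsd-1 had -0.98 ± 0.24, a fall, both with 0.0389. The call for TotC was lost without the ZT4 vehicle array (0.0791), DEX ZT4 replicate 1 (0.116) or 2 (0.113), or vehicle ZT16 replicate 1 (0.12). That of AkhR was lost without any single array but vehicle ZT16 replicate 2, and that of Lsd-1 without any single array but DEX ZT16 replicate 2, with adjusted p over the list up to 0.157 and 0.247, and Lsd-1 had -0.63 without the ZT4 vehicle array. The 17 lists that did not pass for time had camera adjusted p between 0.212 and 0.88, and haemocyte, activity-regulated, muscle and female fat body genes had a median or mean of the opposite sign to the camera direction. None of the core clock genes passed over the list alone. The changes were -1.27 ± 0.40 for tim, -0.54 ± 0.30 for vri, -0.51 ± 0.54 for cwo, -0.40 ± 0.35 for per, -0.19 ± 0.23 for Clk, 0.19 ± 0.24 for cyc, 0.23 ± 0.21 for cry and 0.33 ± 0.33 for Pdp1. Without ZT16 vehicle replicate 2, tim was the 1 core clock gene lower at ZT16 over the list alone, with a limma adjusted p of 0.0475.

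The last comparison asks whether the DEX effect differs between the times. The change of tim was 3.74 ± 0.63 (SE) at ZT4 and 2.85 ± 0.52 at ZT16, and that of per 3.27 ± 0.49 and 2.21 ± 0.40. Among the others, Pdp1 had 0.01 ± 0.56 and 0.49 ± 0.46, cwo 1.39 ± 0.94 and 1.40 ± 0.76, Clk 0.02 ± 0.35 and -0.60 ± 0.29, cyc -0.09 ± 0.40 and -0.49 ± 0.33, and cry 0.12 ± 0.34 and -0.17 ± 0.28. MFS14 had 2.94 ± 0.37 and 2.09 ± 0.30, CG15096 3.02 ± 0.48 and 2.05 ± 0.39, and vri 1.80 ± 0.51 and 1.49 ± 0.41. The change of cwo at ZT16 ran from 0.27 to 2.52 over the arrays left out. No probe set passed limma's adjusted threshold at ZT4, at ZT16 or for the difference. At an unadjusted p under 0.05 there were 450, 315 and 306 probe sets, where chance gives 563 in each. The counts at ZT16 and for the difference hang on single arrays. With ZT16 fitted alone the count was 181, and with a replicate block by number over both times that for the difference was 199. At ZT16 the count was 1774 and 608 without vehicle ZT16 replicates 2 and 1, 780 and 531 without DEX ZT16 replicates 1 and 2, and 193 and 192 without DEX ZT4 replicates 1 and 2. For the difference it was 1263 and 607 without vehicle ZT16 replicates 2 and 1 and 580 without DEX ZT16 replicate 1, and at ZT4 fitted alone it was 863. The difference, ZT16 minus ZT4, was -0.89 ± 0.82 for tim, -1.06 ± 0.64 for per and -0.31 ± 0.65 for vri. Over the arrays left out that of tim ran from -1.50 to -0.29 and that of per from -1.61 to -0.51. The difference was 0.01 ± 1.21 for cwo, 0.48 ± 0.73 for Pdp1, -0.63 ± 0.46 for Clk, -0.40 ± 0.52 for cyc and -0.30 ± 0.44 for cry. The genes with the smallest p for the difference were, with positive values, Fum3 at 0.77 ± 0.11, the prophenoloxidase gene PPO1 at 1.43 ± 0.21, CG14270 at 0.85 ± 0.14, mRpL17 at 1.75 ± 0.29 and smp-30 at 2.28 ± 0.44. With negative values they were CG32669 at -1.49 ± 0.14, Kah at -0.81 ± 0.15, CG8749, a protein of the U1 small nuclear ribonucleoprotein, at -1.48 ± 0.33, CG42249 at -1.94 ± 0.43 and CG15084 at -0.70 ± 0.17. All these differences rest on the single ZT4 vehicle array, which cannot be left out. The DEX mean of Fum3 (2.69) and the vehicle means of CG32669 (2.49) and CG42249 (2.65) lay below the 2.779 of the filter on dim probe sets. The DEX mean of CG14270 (2.81) and the vehicle means of Kah (2.84) and CG15084 (2.80) lay just above it. The sizes of the differences of these genes are therefore uncertain. Across 7971 genes, the DEX effects at the 2 times correlated with a Pearson r of 0.26 and a Spearman rho of 0.08.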

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

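The tests of exchanged labels, of the sampling time, of the share of nervous tissue and of the array that stands apart, and the splits for the correlation between the designs, were chosen after the results were seen; the other splits were not. Of 54 genes kept on both designs and named by the rule for named genes, or called over a list alone for DEX, 11 moved one way on every DEX array with a labelled time against the vehicle arrays and the opposite way on the 4-array table, and 0 moved the same way in both. Chance gives opposite ways for 0.952% of genes not chosen by their p, and most of these were so chosen. These differences between the designs were not tested gene by gene. On the 4-array table the log2 changes were -3.80 for tim, -2.99 for CG15096, -2.47 for MFS14, -2.13 for CG8008, -1.90 for per, -1.75 ± 1.00 (SE) for E(spl)m2-BFM and -1.40 for CG9498, all positive on the arrays with a labelled time. They were 1.48 for dl, 0.97 for CG14567, 0.88 for yin and 0.27 ± 0.19 for CG15515, all negative on the arrays with a labelled time. Those of E(spl)m2-BFM and CG15515 say little, since the former was -0.08 without vehicle replicate 2 and -3.42 without vehicle replicate 3, and the latter 0.06 without DEX replicate 1 and 0.48 without DEX replicate 2. Without vehicle replicate 2 per had -1.09 and CG9498 -0.87, and yin had a vehicle mean of 2.82, below the filter level of 2.924 on this table, so the size of its change is uncertain.

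The pattern is that genes with small p-values for DEX on one design often had the opposite sign on the other. Other splits of the 7 timed arrays cannot decide about chance, here or for the patterns below. They were drawn over all 7 arrays, so many change how many arrays of each time a treatment group holds. Splits that keep these numbers are too few to give a share under 0.05. For the overall correlation, 3 of the 34 splits that can be fitted gave one as large in size. The real split is included here and in the counts below. The size was 0.34 for it and 0.35 for the highest other. A further possible cause is a difference in sampling time between the treatments of the 4-array table, as ZT4 and ZT16 differ. For 15 of the 50 genes with the smallest p for DEX on the arrays with a labelled time, the time change and the DEX change of the 4-array table lay further apart than 2 combined SE (binomial p = 7.38e-05 against 10%). Pdh, with 2.60 for time, had 0.13 ± 0.25 (SE) on the 4-array table. The 50 genes are not independent, and their choice by p in the fit that gives the time errors favours small errors. Pdh is 1 gene picked by its small p for time. As the whole cause, the difference in sampling time is therefore argued against only weakly. As a part of the cause it cannot be told apart from the others, because over these 50 genes both changes correlated at 0.57, 39 with the same sign, though the time change also ran against the DEX change of its own arrays (r -0.76), and over the 50 genes with the smallest p for time, of which none passed, they correlated at 0.05. An exchange of the treatment labels on one of the tables and a true opposite response, at an unlabelled hour or under other conditions, cannot be told apart either, because both give opposite signs, and the 42 of 50 genes with them are the observation that raised the question; the labels were used as given throughout.

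A further pattern is the higher level of core clock genes with DEX on the arrays with a labelled time. Other splits cannot decide about chance for it either. In 3 of 34 the mean change of the list was as large in size, 1.05 for the real split and 1.30 for the highest other. The splits with a larger value change the number of arrays of each time per group. For the number of probe sets at an unadjusted p under 0.05, 22 of 34 splits gave at least the 382 of the DEX comparison, and the highest other gave 2320. That split, which called 657 probe sets after adjustment, in effect sets ZT16 vehicle replicate 1 alone against the other 3 ZT16 arrays, so it points to a structure of the samples, though its calls rest on 1 array without a replicate and the spread of the others. For time, 19 of 34 splits gave at least 402 probe sets, and the highest other gave 1101, with at most 74 after adjustment.

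The last pattern is the higher level of neuronal and phototransduction genes at ZT16. The array that stands apart is argued against as the whole cause, since without ZT16 vehicle replicate 1 the medians were 0.42 for neurons and 0.61 for phototransduction, with camera adjusted p of 1.51e-06 and 2.67e-07 at the preset correlation, though with an estimated correlation neither list passed even with all arrays (0.65 for both). Other splits cannot decide about chance here, for the reason given above. For neurons 2 of 34 gave a median as large (0.36 for the real split, 0.43 for the highest other). For phototransduction 4 of 34 did (0.51 and 0.67). A larger share of nervous tissue and eye in the ZT16 heads would move all members by about 1 amount only if each is expressed there alone. That was not tested. Over all members 9 of 28 neuronal and 5 of 19 phototransduction genes lay further than 2 SE from their median. These counts argue only against an even shift of all members. Many members lie near the floor of the signal with small errors, and over the members with a mean level above 6, a limit chosen after the first counts were seen, 0 of 5 and 1 of 4 (Pdh) did, so a larger share cannot be told apart from regulation.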

How the results depend on the processing

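Array leave-outs for the gene lists and for the correlation between designs, quantile normalization for both, median centring for the lists and the log base were chosen after seeing the data; the cause of the differences was not tested except where fewer arrays are the setting itself. For the DEX effect on the arrays with a labelled time the count stayed at 0 under every alternative but one, with 0 to 18 over the arrays left out, the 18 without DEX ZT16 replicate 2. The replicate numbers gave no sign of pairing the arrays, with deviations of same-numbered arrays correlated at -0.24, -0.01 and 0.07. Only the 0.07 compares groups of the same time, vehicle and DEX at ZT16, so pairing is not excluded. With a replicate block by time and number, or by number over both times, 0 probe sets passed for DEX, and with the block by number over both times 0 passed for time, for ZT4, for ZT16 and for the difference between times, as without it. No paired analysis was possible for the 4-array table because its groups share only 1 replicate number. On that table the count of 1 became 23 without a filter on dim probe sets and 0 with quantile normalization, median centring or array weights, and ran from 0 to 314 over the arrays left out. Time, ZT4, ZT16 and the difference between times stayed at 0 under all their alternatives. The DEX effect at ZT4 without its only vehicle array could not be fitted.

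The lists past the threshold, 2 for DEX on the arrays with a labelled time, became 0 with an estimated correlation or fry, 4 with all probe sets of the lists' genes, 4 over all 8 arrays, and 2 to 6 over the arrays left out. On the 4-array table the 1 list became 0 with an estimated correlation, fry or median centring, and 2 to 6 over the arrays left out. For time the 4 lists became 0 with an estimated correlation or fry, and 2 to 7 over the arrays left out; neurons and phototransduction passed without any single array. The correlation of -0.34 between the designs kept its sign under all alternatives, from -0.45 to -0.15 over the arrays left out. Changes of sign came only in core clock genes that did not pass in that comparison over all probe sets with every array. Over the arrays left out, Pdp1 ran from -0.08 to 0.59 and cry from -0.20 to 0.14 for DEX, vri from -1.20 to 0.79 on the 4-array table, and Pdp1 from -0.06 to 0.61 and cwo from -1.07 to 0.06 for time. At ZT4 cyc ran from -0.24 to 0.06 and Clk from -0.05 to 0.10, and with the replicate block Pdp1 was -0.20 and cyc 0.04. At ZT16 Pdp1 ran from -0.18 to 1.17 and cry from -0.52 to 0.17. For the difference between times cwo ran from -1.12 to 1.13, Pdp1 from -0.20 to 1.15, cyc from -0.82 to 0.02, vri from -0.86 to 0.23 and cry from -0.64 to 0.05. The calls over a list alone for tim, per, vri, MFS14, Gat, Pdp1, Pdh and Cyp6d5 held without any single array, while those of sug, TotC, AkhR and Lsd-1 held in 2, 3, 1 and 1 of 7 such fits. Of the log2 changes of named genes, 6 of 19 for DEX on the arrays with a labelled time, 10 of 20 on the 4-array table, 14 of 33 for time, 3 of 16 at ZT4, 7 of 16 at ZT16 and 7 of 18 for the difference moved by over 1.5 times or changed sign with a single array left out. With log2 of the deposited values the change of tim would be 4.63 and -5.49. Signal over background limits the dim probe sets, whose values lie near a floor.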

Other observations

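The tests and genes here were chosen after their values were seen. None of the genes of this paragraph passed limma's threshold for DEX over all probe sets on either design. Picot, a phosphate transporter gene, had a log2 change of 1.79 ± 0.31 (SE) on the arrays with a labelled time and -1.36 ± 0.62 on the 4-array table. The alkaline phosphatase genes Alp10, Alp9 and Alp4 had 2.45 ± 0.95, 2.49 ± 1.05 and 1.20 ± 0.25, against -2.83 ± 0.56, -1.89 ± 0.70 and -0.13 ± 0.13 on the 4-array table. The remaining measured members did not follow, with -0.02 for Alp11, 0.04 for Alp12 and -0.10 for Alp13. The family was tested because 3 of its members had been seen to be higher, so the test cannot show a response of the family. Over the 6 members camera gave p = 0.00797 with the preset correlation and p = 0.122 with an estimated correlation, and over the 5 members kept on the 4-array table, all with negative changes, p = 0.00221 and p = 0.0891. Further genes with the same pair of signs as tim were fbl, a pantothenate kinase, at 1.77 ± 0.31 and -0.86 ± 0.35, and the zinc finger gene sugarbabe (sug) at 2.13 ± 0.46 and -1.50 ± 1.43.

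MFS14 and CG15096, with changes of 2.43 and 2.44 on the arrays with a labelled time, are neighbouring genes in the RefSeq table of Release 6 plus ISO1 MT. A change over the whole region is a possible explanation that the flanking genes argue against. Of the 10 protein-coding genes around the pair, 5 on each side, 7 had a kept probe set, and the largest change in size among them was 0.59, for CG15097.

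The vehicle array without a labelled time in the 8-array table had levels of 6.59 for tim, 7.20 for per and 9.65 for MFS14. On the 3 vehicle arrays with a labelled time the ranges were 5.49 to 6.70, 7.62 to 7.96 and 9.24 to 9.73.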
